A study of Mus musculus with 2 samples.

How the data were processed

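Gene expression was measured in hippocampal microglia of mice at 3 weeks after birth, in 1 Control and 1 FGR library. Per the labels' protocols, Tmem119-positive cells were sorted by flow cytometry and made into 10x Genomics single-cell 3′ libraries. The deposited values are raw UMI counts per gene and barcode, with no normalization and no filter on cells, in matrices written by Cell Ranger 4, per the file headers. Cell Ranger 3.0, Seurat 5.0 and the mouse genome build mm10 are named per the submitters' processing notes, so the notes and the headers differ on the Cell Ranger version. The gene annotation and whether counting used strand are not given in the sources used here. Groups were taken from the sample titles.

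The matrices held 1961707 barcodes for the Control library and 1935841 for the FGR library, over 32285 gene IDs. Of these IDs, 32158 were found in the GENCODE M21 annotation of the same build (GRCm38), which gave the coordinates. Counts of 38 symbols held by more than 1 ID, such as Ddit3, were summed, and transcripts of overlapping genes may be assigned to either. A barcode was called a cell when its UMI total reached 0.1 of the 99th percentile of the 3000 barcodes with the most UMIs, which came to 1492 UMIs in the Control library and 1516 in the FGR library. This left 10706 and 8642 barcodes. Of these, 3 and 1 were removed for fewer than 200 genes, and 16 and 27 for more than 10% mitochondrially coded UMIs. Cells held 90.8% and 89.4% of all UMIs. Scrublet, run per library with an expected rate of 0.06, called 1 and 0 doublets. A caller that marks so few of this many cells has not worked, so doublets remain in the data. An alternative left out the 6% of cells with the highest scores.

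Both libraries were clustered together without batch correction (log-normalised counts, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, fixed seeds). A cluster was called microglia-like when at least 3 microglial markers were detected in at least 20% of its cells, no other type had a larger share of its markers detected, and its 10 leading genes by fold held no more markers of another type than of microglia. Leading genes were taken only among genes detected in at least 10% of a cluster's cells, a rule set after the data were seen, because a few stray cells of another type could otherwise lead a cluster's means. The clusters kept out of the class hold 4.29% of the Control cells and 2.08% of the FGR cells. Names rebuilt in this way may differ from the study's own.

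UMI counts were summed over the microglia-like cells of each library (51381433 UMIs in the Control library and 44633658 in the FGR library) and scaled to counts-per-million (CPM). With 1 library per group no test was possible. Levels have exact Poisson intervals, ratios (FGR over Control) exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95% and covering counting error only. Among named genes of at least 50 CPM the widest half-width of a level's interval was 4.13%. A gene passed the rule of size when it reached 50 CPM in at least 1 library and the interval of its ratio lay wholly above 1.5 or below 1/1.5. The median log2 ratio of the 3508 genes measured was -0.06. For each list with at least 5 genes measured, the median log2 ratio was placed among 10000 random lists of the same size, each gene drawn from the 50 nearest in mean expression, as a description of these libraries. Cycling cells held at least 3 UMIs of 18 proliferation genes after thinning each cell to 2000 UMIs.

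The design, the 23 gene lists, the cell type markers and the genes to name were chosen before the data were examined, apart from what is said here and in the closing parts to have been added later. The genes named are, of those past the rule of size, the 12 with the largest and the 12 with the smallest ratio (leaving out predicted, ribosomal and sex-linked genes), up to 4 measured members of each list with the largest absolute log2 ratio, and 15 microglial and inflammatory genes given in every case. The remaining glucocorticoid list members, Ccl3, Dnajb1, Gm22146 and G530011O06Rik were named after their values were seen. Clec7a, Mx1 and Lrrc33 (an older name of Nrros) are not analysed here, and a few genes that the rule would name are not reported here.

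On simulated data for the comparison of FGR with Control summed cells (3386 genes, 200 of them changed), 100% of 50 genes set 2-fold higher and 100% of 50 set 2-fold lower passed the rule, and 0% of the genes set 1.2-fold higher or lower did. No unchanged gene passed, and 95.1% of intervals held the true ratio. The simulated counts held counting error only, the error that the intervals assume, with no variation between libraries or cells. They therefore check the calculation and do not show how many passing genes would recur in other libraries. Of 100 random lists, 6 lay outside their range.

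Alternatives covered the UMI and mitochondrial limits, doublets, clustering, scaling, thinning, equal weight per cell, subtraction of free RNA (profile from barcodes of 10 to 100 UMIs, share from 78 non-microglial markers, which gave 4.15% for the Control library and 14.9% for the FGR library), the CPM minimum, the ratio bound, and subsets of cells. These free RNA shares are upper bounds, because cells of other types also bring the markers. Haemoglobin in cells was only 2.80% and 1.84% of its level in those barcodes, so both shares are too high, the FGR share by more. Values with free RNA subtracted are therefore over-corrected in both libraries. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9 were used.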

Results

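Microglia, the resident immune cells of the brain, were profiled by droplet-based 3′ single-cell RNA sequencing from the hippocampus of mice at 3 weeks after birth. The data comprised 2 libraries, 1 from Control mice and 1 from mice with fetal growth restriction (FGR), a condition of impaired growth before birth. The mice were heterozygous for Tmem119-tdTomato, a red fluorescent reporter of Tmem119, which microglia express and most other brain cells do not. Cells positive for Tmem119 had been sorted by flow cytometry. How many animals went into each library is not given in the sources used here. The Control library held 58988805 unique molecular identifiers (UMIs, 1 per captured transcript molecule) over all barcodes and the FGR library 50833332. After cell calling, 10686 Control cells and 8614 FGR cells remained, with medians of 4657 and 4920.5 UMIs and of 2057 and 2068 genes per cell. The median share of mitochondrially coded UMIs was 1.94% and 1.95%. Each group was 1 library, so no difference below has a replicate check and none was tested. The 95% intervals cover counting error only, and higher or lower describes these 2 libraries.

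The first question was which cells the sorted populations held. Microglia-like cells made up 95.7% of the Control cells (10228 cells, Clopper-Pearson interval 95.3 to 96.1%) and 97.9% of the FGR cells (8435 cells, 97.6 to 98.2%). All 12 microglial markers were detected in every cluster counted as microglia-like. The sort for Tmem119 sets these shares in part, and they depend on the clustering. With the 1 called doublet kept, a cluster of 3869 Control and 557 FGR cells was no longer named, and the shares were 59.5% and 91.6%. Cells left outside numbered 458 in the Control library and 179 in the FGR library. Most of the former, 382 cells or 3.57% of the Control library, formed a cluster led by Mbp and Mobp, which encode myelin proteins of oligodendrocytes, against 15 cells or 0.174% of the FGR library. That cluster also carried all 12 microglial markers. Summed over 78 markers of astrocytes, oligodendrocytes, neurons, vascular cells and other non-microglial types, the level in microglia-like cells was 563.2 CPM (UMI counts-per-million) in the Control library and 533.1 in the FGR library.

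The joined libraries fell into 13 clusters, and the 4 largest were each nearly from 1 library. Clusters 0 and 1, led by Hes1 and by Sertad1, held 4490 and 4497 Control cells but 140 and 76 FGR cells. Clusters 2 and 3, led by Tnfaip3 and by the predicted gene Gm22146, held 4216 and 2896 FGR cells but 46 and 128 Control cells. A cluster mostly of 1 library may be that library rather than a cell state, so the sizes of these clusters are not compared. Values for microglia-like cells below therefore compare mainly clusters 0 and 1 with clusters 2 and 3. Cells were assigned to clusters by expression, so ratios within a cluster are in part set by that assignment. They are not an independent check of the summed values. Clusters holding cells of both libraries were led by Csf1 and Lgals3 (cluster 4, 580 Control and 586 FGR cells), by nuclear and mitochondrial transcripts at low depth (cluster 5, 203 and 344 cells), by interferon-induced genes such as Ifit3 (cluster 7, 146 and 76 cells), by satellite-like predicted genes (cluster 8, 115 and 80 cells) and by mitotic genes such as Top2a (cluster 11, 23 and 21 cells).

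**Figure D1:**
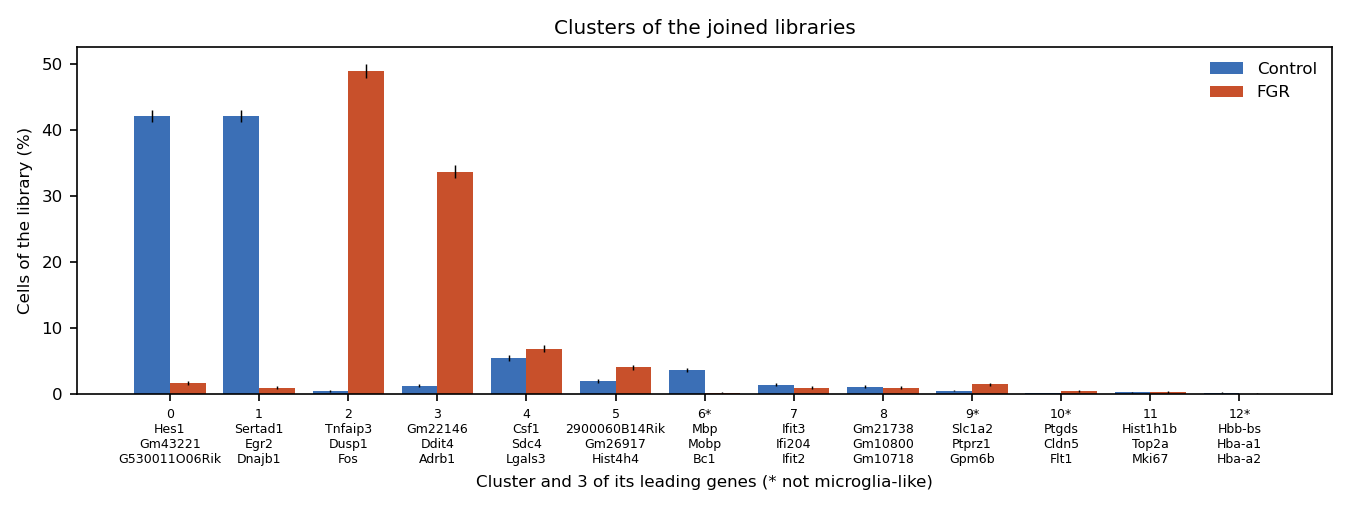
Share of each library's cells in each of the 13 clusters of the joined libraries, with exact Clopper-Pearson 95% intervals (counting error only). Clusters marked with an asterisk were not counted as microglia-like; clusters 0 and 1 hold 42.0% and 42.1% of the Control cells, and clusters 2 and 3 hold 48.9% and 33.6% of the FGR cells.

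The main comparison asked which transcripts differed in level between microglia of the FGR and Control libraries. Most did not differ much. Of 3508 genes measured, meaning a level of at least 50 UMI counts-per-million (CPM) in at least 1 library, 95.7% had a ratio between 1/1.5 and 1.5, and levels correlated across genes with a Spearman coefficient of 0.956 (genes are not independent replicates). By a fixed rule of size, the whole interval of the ratio beyond 1.5-fold, 87 genes were higher and 41 were lower in the FGR library. They are genes past a rule of size between 2 libraries, not genes shown to respond to growth restriction. Their number depended on the cells included. Within cluster 0 alone, the largest, 21 were higher and 14 lower.

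Among the 12 genes with the largest ratios were stress and signalling genes. Coordinates are those of the whole gene in GRCm38 (mm10), and all genes given with coordinates are protein-coding, apart from Gm22146, which is annotated as antisense. Cxcl10, an interferon- and NF-kB-induced chemokine (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), stood at 158.9 CPM in the FGR library and 21.6 in the Control library, a ratio of 7.36 (6.91 to 7.85). Hspb1, a small heat shock protein, stood at 56.5 against 8.51 CPM, a ratio of 6.65. Ddit4, a stress-induced inhibitor of mTORC1 that is also induced by glucocorticoids and hypoxia (ENSMUSG00000020108, chromosome 10, 59949669 to 59951834), stood at 305.9 against 52.0 CPM, a ratio of 5.88 (5.64 to 6.13). Dusp1, a phosphatase that switches off MAP kinases (ENSMUSG00000024190, chromosome 17, 26505590 to 26562128), stood at 2739 against 580.8, a ratio of 4.72 (4.66 to 4.78). The linker histone genes Hist1h1d and Hist1h1c had ratios of 5.07 and 4.58. The transcriptional regulator Id2 had a ratio of 4.52 and the NF-kB inhibitor Tnfaip3 of 4.19. Ccrl2, Rcan1 and the β1-adrenergic receptor gene Adrb1 followed at 3.60, 3.52 and 3.31. Most of these ratios were smaller within clusters 0 and 3, which have 140 FGR and 128 Control cells. Tnfaip3, Dusp1, Hist1h1c, Ccrl2 and Rcan1 are among the genes that lead cluster 2, which held 4216 FGR cells. FGR cells high in them tend to fall there, so smaller ratios in clusters 0 and 3 are in part set by the clustering. There Dusp1 had 2.19 and 2.20, Id2 1.70 and 1.77, Tnfaip3 1.499 and 1.36, Hist1h1c 1.58 and 1.44, and Hist1h1d 1.54 (0.975 to 2.31) and 1.77. Within clusters 4 and 5 Dusp1 had 3.54 and 5.22, Id2 2.41 and 1.89, Tnfaip3 3.98 and 2.77, Hist1h1c 3.14 and 1.63, and Hist1h1d 2.83 and 1.75 (0.966 to 3.32). Ddit4 lay between 3.78 and 4.04 in all 4. In clusters 0 and 3 Cxcl10 had 0.693 (0.297 to 1.38) and 2.52, and Ccrl2 0.920 (0.709 to 1.17) and 0.899 (0.736 to 1.11). In cluster 4, with similar numbers of cells from both libraries, Cxcl10 and Ccrl2 had ratios of 4.46 (3.88 to 5.15) and 2.36 (2.12 to 2.62).

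Among the 12 genes with the smallest ratios, Hbb-bs, a globin gene of red blood cells, stood at 11.3 CPM in the FGR library and 55.7 in the Control library, a ratio of 0.203 (0.184 to 0.223). Its level in barcodes of 10 to 100 UMIs, which hold free RNA rather than cells, was 631.8 and 1977. Mid1, a ubiquitin ligase gene of the distal X chromosome (ENSMUSG00000035299, 169685199 to 170005736), stood at 12.6 against 55.2 CPM, a ratio of 0.229 (0.208 to 0.250). Its span holds the non-coding gene G530011O06Rik, so reads of the pair may not be fully separable. Hes1, a transcriptional repressor downstream of Notch (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796), stood at 65.1 against 235.9, a ratio of 0.276 (0.265 to 0.287). Sertad1, Rsrp1 and Dusp7 followed at 0.396, 0.412 and 0.424, and the early response transcription factor gene Egr2 at 0.457. The blood and myeloid transcription factor gene Hhex had a ratio of 0.493 and Hexim1, an inhibitor of transcription elongation, of 0.496. Marcksl1, Nabp1 and Cdk5r1 lay between 0.514 and 0.532. Within clusters 0, 3, 4 and 5, the intervals of Hes1, Rsrp1, Dusp7, Hhex and Cdk5r1 lay below 1. Intervals that held 1 were those of Sertad1 (ratios 0.812 and 1.09), Egr2 (0.682 and 0.762), Marcksl1 (0.968 and 0.934) and Hbb-bs (1.38 and 0.635) in clusters 3 and 5, and of Hexim1 (0.7996 and 0.938) in clusters 0 and 5. Nabp1 had 1.21, 1.03 and 1.25 in clusters 0, 3 and 5, also with intervals that held 1, and 0.601 (0.511 to 0.706) in cluster 4. A further 7 genes past the rule were predicted or unnamed transcripts, 6 of them higher and 1 lower in the FGR library.

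**Figure D2:**
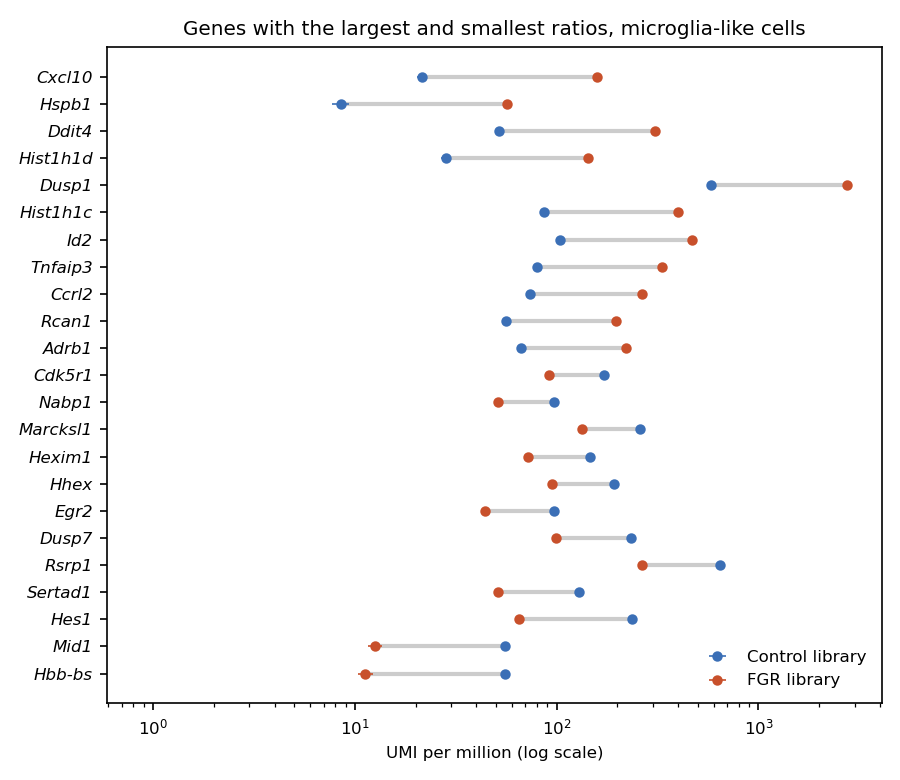
Levels (CPM, log scale) in microglia-like cells of the Control and FGR libraries for 11 of the 12 named genes with the largest ratio and the 12 with the smallest. Bars are exact Poisson 95% intervals, mostly smaller than the points; Cxcl10 goes from 21.6 in the Control library to 158.9 in the FGR library, and Hbb-bs from 55.7 to 11.3.

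Genes of the glucocorticoid response, a list fixed in advance, were higher together in the FGR library. Of 10 members measured, 7 were higher by the rule of size and 0 lower, and the median log2 ratio of 1.06 lay at percentile 100 among 10000 random lists matched on expression. Besides Ddit4 and Dusp1, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), stood at 561.6 against 189.3 CPM, a ratio of 2.97 (2.90 to 3.04). Fkbp5, a co-chaperone that dampens the glucocorticoid receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), had a ratio of 2.11 (2.06 to 2.16), the kinase gene Sgk1 of 2.17 and the clock gene Per1 of 2.07. Txnip, an inhibitor of thioredoxin and of glucose uptake, had a ratio of 1.85. Cdkn1a, the receptor gene Nr3c1 and Errfi1 had ratios of 1.09, 0.955 and 0.838. Dusp1 also stands on the immediate early list and Ddit4 on the hypoxia list. The median was 0.73, 0.96, 0.88 and 1.40 within clusters 0, 3, 4 and 5, the clusters with at least 100 cells of each library. At 2000 UMIs per cell and without Dusp1, it was 1.01, 0.94, 0.84 and 1.01 in 4 strata of cells with rising immediate early UMIs.

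**Figure D3:**
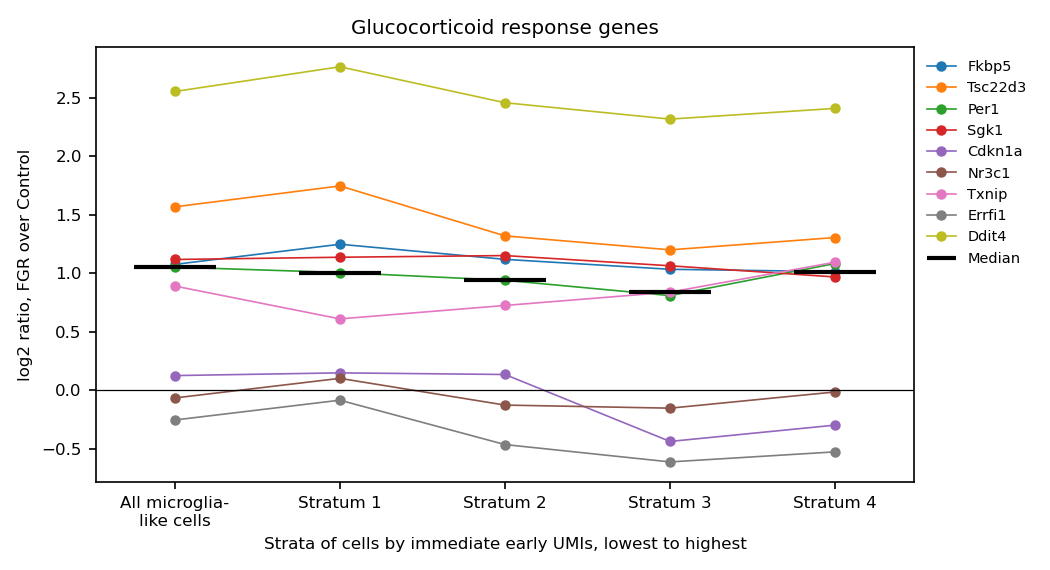
log2 ratio, FGR over Control, of 9 glucocorticoid response genes (points and lines, without Dusp1) and their median (black bars), in all microglia-like cells and in 4 strata of cells thinned to 2000 UMIs and grouped by their immediate early UMIs. The medians of the strata lie between 0.84 and 1.01.

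Immediate early genes, which switch on within minutes of stimulation and also during cell dissociation, were more often higher than lower in the FGR library. Of 26 measured, 12 were higher and 2 lower by the rule of size, with a median log2 ratio of 0.51 at percentile 100. The AP-1 gene Fos stood at 4287 against 1985 CPM (ratio 2.16), and Rgs1, a brake on G protein signalling, had a ratio of 2.62. Egr2 and the heat shock co-chaperone gene Dnajb1, at 0.457 and 0.535, were the members lower in the FGR library. Within clusters 0, 3, 4 and 5 the list's median was 0.01, 0.18, 0.30 and 0.42.

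Of 16 measured inflammatory cytokine and NF-kB target genes, 5 were higher and 0 lower in the FGR library. These were the chemokine genes Ccl3 and Ccl4 (ratios 1.75 and 2.28), the surface protein gene Cd83 (2.76), and Nfkbia and Tnfaip3, which encode inhibitors of NF-kB (2.60 and 4.19). The tumour necrosis factor gene Tnf had a ratio of 1.14. Il1b, at 11.2 CPM in the FGR library and 7.84 in the Control library, lay below the minimum. The list's median of 0.18 lay at percentile 99.99, but it was -0.0793 in cells matched on immediate early UMIs and -0.014 with the 1 called doublet kept. Within clusters 0, 3, 4 and 5 it was -0.39, -0.34, 0.38 and -0.033. By the rule of size 1 member was higher and 2 were lower in cluster 0, 1 and 2 in cluster 3, 5 and 0 in cluster 4, and 3 and 1 in cluster 5. The ratio of Ccl4 turned to 0.709 (0.657 to 0.763) in cluster 0 and 0.746 (0.708 to 0.785) in cluster 3, and that of Cd83 was 1.22 and 0.872 there, with intervals that held 1. Of 13 genes of anti-inflammatory and TGF-β signalling, Socs3, a feedback inhibitor of cytokine signalling, was higher with a ratio of 2.56 and 0 were lower. Within clusters 0 and 3 the ratio of Socs3 was 1.15 (0.975 to 1.34) and 1.02 (0.882 to 1.18), and within clusters 4 and 5 it was 1.76 (1.59 to 1.95) and 1.60 (1.19 to 2.17). Tnfaip3, Socs3 and Cd83 are among the genes that lead cluster 2, so FGR cells high in them tend to fall outside clusters 0 and 3. Nrros, which encodes a protein that holds and activates TGF-β, had a ratio of 0.670, and the list's median was 0.02.

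Homeostatic microglial genes showed little difference in the summed cells. Of 20 measured, 0 passed the rule of size in either direction, and the median was -0.06, at percentile 22.5. Within clusters 0, 3, 4 and 5 the list's median was -0.02, -0.02, -0.23 and -0.17, with 1 member lower by the rule of size in cluster 4. Tmem119 stood at 962.3 CPM in the FGR library and 912.2 in the Control library (ratio 1.05), and Csf1r and Cx3cr1 had ratios of 1.02 and 0.893. The purinergic receptor gene P2ry12 had a ratio of 0.802 and Sall1, a transcription factor of microglial identity, of 0.674. Of 12 measured genes of disease-associated or axon-tract microglia, only the growth factor gene Csf1 was higher, with a ratio of 2.28. Within clusters 0 and 3 its ratio was 0.964 and 0.957, with intervals that held 1, and within clusters 4 and 5 it was 1.56 (1.44 to 1.70) and 3.49 (1.19 to 13.9). Apoe and Trem2 had ratios of 1.03 and 1.09. Spp1, at 12.5 against 6.15 CPM, and Igf1, at 7.06 against 6.77, lay below the minimum. The list's median was 0.10, at percentile 98.97, and 0.12, -0.17, 0.17 and 0.13 within clusters 0, 3, 4 and 5.

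Genes of complement and phagocytosis and of the lysosome differed by small ratios. Of 21 measured in the former list, C5ar1, the receptor for complement fragment C5a, was higher with a ratio of 1.61 and 0 were lower. C1qa stood at 7126 against 6481 CPM, and the list's median was 0.09, at percentile 99.79. That median was 0.06, 0.03, -0.01 and 0.07 within clusters 0, 3, 4 and 5. Of 25 lysosomal genes, 0 passed the rule, with a median of -0.01. Cd68 had a ratio of 0.979 and Ctsh of 1.29. Of 8 measured MHC class I genes, H2-T23 was higher with a ratio of 1.58, H2-D1 and H2-K1 had ratios of 1.34 and 1.28, and the median was 0.22 at percentile 99.97. The MHC class I median was 0.21, 0.006, 0.18 and 0.42 within clusters 0, 3, 4 and 5. Only 2 MHC class II genes and 3 interferon response genes were measured. Besides Cxcl10, which was higher, the interferon genes Bst2 and Trim30a had ratios of 1.23 and 0.964. Summed over 21 interferon response genes, the level was 587.0 CPM in the FGR library and 406.5 in the Control library, of which Cxcl10 made up most of the difference. Without it the sums were 428.1 and 384.9. Over 7 MHC class II genes the sums were 258.5 and 190.9. Of the sex-linked list, the Y-linked genes Ddx3y and Eif2s3y were measured, with ratios of 0.893 and 0.951.

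Medians of metabolic lists were small, though some lay outside the random range. They were 0.14 for 11 glycolysis genes (percentile 99.94), 0.05 for 23 nuclear-coded oxidative phosphorylation genes (percentile 99.72), 0.02 for 13 mitochondrially coded genes and -0.05 for 28 ribosomal protein genes. In each of these, 0 members passed the rule. The oxidative phosphorylation median turned to -0.019 once free RNA was subtracted. Among 7 lipid handling and 10 oxidative burst and antioxidant genes 0 passed, with medians of 0.02 and -0.10. Of 6 measured hypoxia genes Ddit4 alone was higher, Hif1a had a ratio of 1.06, and the list's median was 0.05. Of 11 ER stress genes, Ddit3, a transcription factor of that response, was lower with a ratio of 0.598, and Atf4 had a ratio of 0.683, while the list's median was 0.11, at percentile 98.52. The ER stress median was 0.10, 0.03, -0.06 and 0.05 within clusters 0, 3, 4 and 5. Of 6 trophic factor genes, Csf1, Gdf15 and Osm were higher, with ratios of 2.28, 2.01 and 1.67, while Pdgfb had a ratio of 0.799. Within clusters 0 and 3 the intervals of Csf1, Gdf15 and Osm held 1, while in cluster 4 Gdf15 had a ratio of 2.04 (1.77 to 2.35) and Osm of 1.63 (1.42 to 1.88). That list's median of 0.32, at percentile 99.67, changed sign under 7 of 18 alternatives. It was -0.29, -0.34, -0.036 and -0.39 within clusters 0, 3, 4 and 5, where 3, 5, 8 and 4 members were measured. No cholesterol synthesis gene reached the minimum, and the 15 genes summed to 193.7 against 218.7 CPM. Of 19 lists with at least 5 genes measured, 10 had a median outside the central 95% of random lists.

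**Figure D4:**
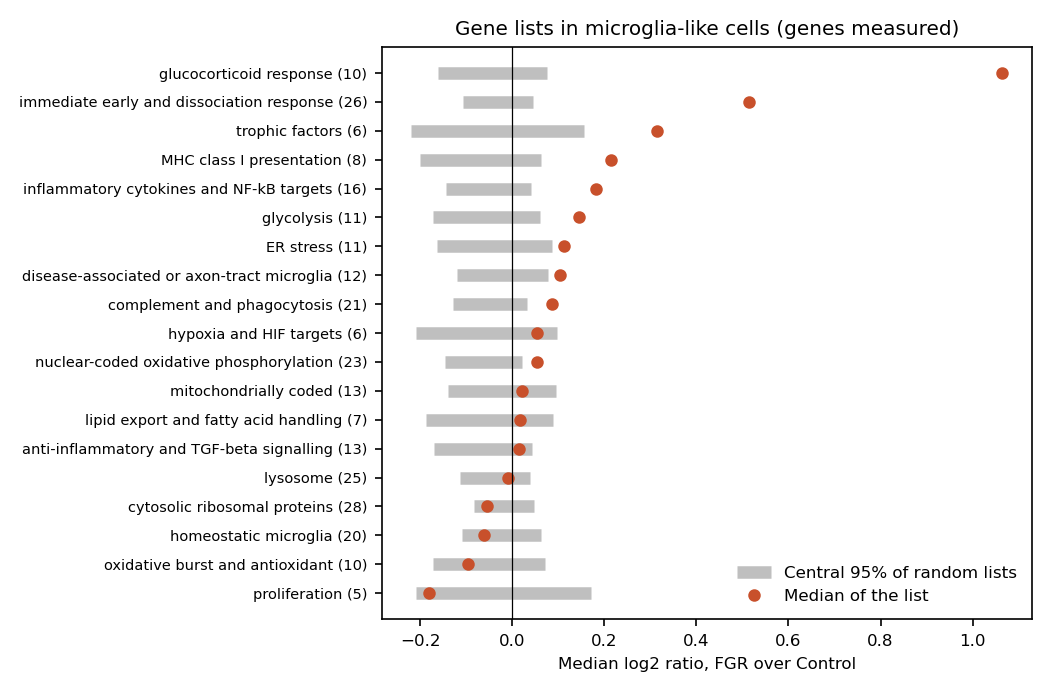
Median log2 ratio, FGR over Control, of the 19 gene lists with at least 5 genes measured (points; genes measured in parentheses) against the central 95% of 10000 random lists matched on expression (grey bars). The glucocorticoid list at 1.06 and the immediate early list at 0.51 lie farthest out.

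Whether proliferation differed was examined at equal depth. Thinned to 2000 UMIs per cell, 1.19% of Control (0.987 to 1.42%) and 1.23% of FGR microglia-like cells (1.004 to 1.49%) held at least 3 UMIs from 18 proliferation genes. These intervals overlap. At a minimum of 2 UMIs the shares were 6.71% (6.23 to 7.21%) and 5.41% (4.94 to 5.92%), lower in the FGR library with intervals that did not overlap, so the comparison depends on the minimum. Thinning left out 134 Control and 141 FGR cells. Without thinning the shares were 10.3% and 9.27%, at median depths of 4668 and 4936 UMIs. In the cluster with vascular markers, 0 of 11 and 0 of 40 thinned cells reached 3 UMIs, which allows shares of up to 28.5% and 8.81% by the exact interval (median depths 5977 and 6721 UMIs). Without thinning, 0 of 11 and 4 of 41 did, the latter 9.76% (2.72 to 23.1%). Mki67, a marker of dividing cells, stood at 5.002 and 5.086 CPM. Of 5 proliferation genes measured, 0 passed the rule of size, and their median was -0.18, at percentile 5.38. They include Hmgb2, Tubb5 and H2afz, which are not among the 18 genes used to count cycling cells.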

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

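Both results below concern a cluster outside the comparison of microglia that held a larger share of the FGR library than of the Control library. All cells outside that comparison together were 4.29% of the Control cells and 2.08% of the FGR cells. Cluster 9, with Slc1a2 and Ptprz1 among its leading genes, held 1.42% of the FGR cells (122 cells, 1.18 to 1.69%) and 0.487% of the Control cells (52 cells, 0.364 to 0.638%). Its content differed between the libraries. Summed over 8 markers of oligodendrocytes, without a further marker that is not reported here, the level was 5128 CPM in its FGR cells and 571.2 in its Control cells. Markers of immature neurons summed to 216.5 and 1330 CPM, and markers of astrocytes to 2230 and 1549. Cluster 10, led by the vascular and fibroblast genes Ptgds, Cldn5 and Flt1, held 0.476% of the FGR cells (41 cells, 0.342 to 0.645%) and 0.103% of the Control cells (11 cells, 0.0514 to 0.184%). The cells had been sorted for Tmem119, and microglial markers were detected in both clusters, 12 in cluster 9 and 11 in cluster 10. No explanation of either was tested.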

How the results depend on the processing

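Chosen after seeing the data were the clustering centred within each library, the removal of the highest doublet scores, the cells matched on immediate early UMIs, the cells of at least 3000 UMIs and the clusters with 100 cells of each library. No paired analysis was possible because each group is 1 library, and for that reason no replicate could be left out and no other split of samples made. Cells called ranged from 10124 to 10949 (Control) and from 8108 to 8940 (FGR) over 6 alternatives. Of 39 single genes followed, 28 had the same sign under every alternative run. The glucocorticoid median ranged from 0.73 to 1.13 over 18 alternatives and the immediate early median from 0.01 to 0.58. Unless stated, the cause of a change was not tested.

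The microglia-like share was 97.6% (FGR) at resolution 1.0, 95.2% (Control) with variable genes without 5 lists, 92.0% (Control) and 93.4% (FGR) after centring, 96.5% and 99.4% at a minimum of 500 UMIs, 97.4% (FGR) at 1000 UMIs and 98.7% (FGR) at 5% mitochondrial UMIs. With the 1 doublet kept it was 59.5% (Control) and 91.6% (FGR), because naming then left out a cluster of 3869 Control and 557 FGR cells whose first leading gene was the astrocyte marker Slc1a2. The class therefore rests on a naming rule that 1 cell can tip. Genes lower in the FGR library then numbered 84, and the NF-kB median was -0.014.

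Genes lower numbered 68 at a minimum of 20 CPM, 8 at a ratio bound of 2, 14 in the largest cluster and 17 in clusters with 100 cells of each library. Genes higher numbered 57 at a minimum of 100 CPM (fewer genes measured), 38 at a bound of 2 and 21 in the largest cluster. There, 5 lists lay outside the random range, the NF-kB median was -0.39, the trophic median -0.29, and the log2 ratios of Cxcl10, Ccrl2 and Nabp1 were -0.53, -0.12 and 0.28, each with an interval of the ratio that held 1. The NF-kB median was -0.0793 in cells matched on immediate early UMIs. The trophic median was -0.025 with the total taken without mitochondrial, ribosomal, haemoglobin and immediate early genes, -0.11 in thinned cells, -0.12 with equal weight per cell, -0.069 with free RNA subtracted, -0.32 at a minimum of 100 CPM and -0.13 in cells with 0 cycling UMIs. The oxidative phosphorylation median was -0.019 with free RNA subtracted, an over-correction in both libraries. Cycling shares (Control and FGR) were 6.71% and 5.41% at 2 UMIs, 0.277% and 0.289% at 5 UMIs, and 10.3% and 9.27% without thinning. The interferon cluster held 0.882% of FGR cells, and 1.14% after centring.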

Other observations

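The tests of myelin and haemoglobin RNA, the test of sex and the genes of the next paragraph were chosen after the results were seen.

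Some genes were singled out after their values were seen, with no fixed list and no test of a group. Among linker histone genes, which encode proteins that bind DNA between nucleosomes, Hist1h1e stood at 460.4 CPM in the FGR library and 172.6 in the Control library (ratio 2.67, 2.60 to 2.74), and H1f0 at 65.4 and 34.7 (ratio 1.88). H3f3b, which encodes the replacement histone H3.3, had a ratio of 2.01, while H3f3a, which encodes the same protein, had a ratio of 0.875. The annotated transcript Gm22146 (chromosome 17, 28446500 to 28456457) lies inside Fkbp5 on the opposite strand and stood at 70.2 against 6.09 CPM, a ratio of 11.5 (10.3 to 12.99). Whether counting used strand is not given in the sources used here, so its reads and those of Fkbp5 are not known to be separable.

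The glucocorticoid genes that were higher in the FGR library were weighed first. Matching cells on immediate early UMIs left a mean median of 0.9502, though stratum 4 stayed uneven (means of 127.0 UMIs in Control and 144.8 in FGR cells). Subtracting free RNA, at shares that over-correct both libraries, left 0.994. Within clusters 4 and 5, which hold both libraries but a small part of the cells, the lowest median was 0.882 (0.73 in cluster 0). A stronger immediate early response or free RNA at those shares alone is therefore unlikely to be the whole source. The same holds for the mix of cell states, as far as these clusters show. A different time of day stays open, because only 1 of 11 clock genes, Clock, reached 50 CPM (ratio 0.998), too few for the bound of 3 genes set for it. Below that level 4 differed by more than 1.5-fold in both directions, Nr1d1 (1.71), Ciart (1.69), Per3 (0.581) and Nr1d2 (0.657), and only Per3 did so with its whole interval. With 1 library per group, fetal growth restriction cannot be told apart from handling, litter, sampling time or library.

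Myelin and haemoglobin RNA were higher in the Control library, at 56.3 against 31.6 CPM for Mbp and Mobp and 102.9 against 25.3 CPM for haemoglobin genes in microglia-like cells. Free RNA stays open for myelin. Its UMIs had a variance of 1.70 times their mean over Control microglia-like cells at equal depth. That lies between the bounds of 1.5 for evenly spread RNA and 3 against it. With the cells of the myelin cluster it was 3.27, past the bound of 3. The test was moved to microglia-like cells alone after both values were seen. The cluster left out was led by Mbp and Mobp, which lowers the variance of the rest, so the test cannot decide. In barcodes of 10 to 100 UMIs Mbp and Mobp stood at 8156 CPM in the Control library and 1259 in the FGR library (ratio 0.154, against 0.562 in the cells). Doublets with oligodendrocytes stay open, since cells of that cluster had 0.961 times the median UMIs of microglia-like cells, but 8 other oligodendrocyte genes also stood at 139.8 against 59.9 CPM there (2.33 times, and Mbp and Mobp 27.4 times). Haemoglobin RNA may in part be free RNA. Its level in cells, as a share of that in barcodes of 10 to 100 UMIs, differed by 1.52 times between the libraries. In the Control library that share was 2.80%, from 102.9 CPM in cells and 3676 in those barcodes. Mbp and Mobp had a smaller share there, 56.3 against 8156 CPM. Evenly spread free RNA of that make-up would thus not supply all haemoglobin RNA of the Control cells. In the FGR library haemoglobin had the smaller share, 25.3 against 1373 CPM, with 31.6 against 1259 for Mbp and Mobp. These levels leave out a cluster led by Hbb-bs, Hba-a1 and Hba-a2, of 13 Control cells and 1 FGR cell. It was not counted as microglia-like, though all 12 microglial markers were detected. Erythroid markers summed to 16040 CPM in its Control cells. Microglia that had taken up myelin, or adhering fragments, stay open and were not tested, and no biological explanation was tested.

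Mid1 and the transcript G530011O06Rik inside it (ratio 0.112) were lower in the FGR library. Within clusters 0, 3, 4 and 5 the ratio of Mid1 lay between 0.151 and 0.296. A difference in sex is unlikely, since the Y-linked gene farthest from equal, Ddx3y, had a ratio of 0.893 and Xist had 4 and 5 UMIs. Ddx3y stood at 110.5 CPM in the Control library and 98.6 in the FGR library, and Xist at 0.078 and 0.11. The cells of both libraries thus look nearly all male, which argues against a difference in sex. Of 4 neighbours, which summed to a ratio of 0.929, only Msl3 (0.863) and Hccs (0.980) had more than a few UMIs, both below 50 CPM. Msl3 and Hccs did not fall by 1.5-fold, but they cannot speak for the rest of that stretch, which stays open. A strain difference between the animals of the libraries, or reads assigned differently there, stays open and was not tested.

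Transcripts known to be carried into neuronal dendrites, 7 genes listed after the data were seen, summed to 12.8 CPM in the FGR library and 34.4 in the Control library, against 34.7 and 50.5 for 11 other neuronal genes. Most of the sum was Bc1 (6.92 and 15.6 CPM) and Camk2a (3.58 and 10.5 CPM), which were also lower in barcodes of 10 to 100 UMIs of the FGR library (ratios 0.410 and 0.395).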
